A study of Mus musculus with 4 samples.

How the data were processed

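Gene expression was measured in regenerating mouse liver on 4 single-colour Affymetrix arrays, 2 from mice given human bone marrow stromal cells that expressed EGFP (a green fluorescent protein, the control) and 2 from mice given the same kind of cells that expressed OGFRL1. Per the labels, biotin-labelled cRNA was made from 100 ng of total RNA per array. Per the submitters' processing notes, the software was MAS5, whose version is not given in the sources used here, and neither are the scanner and the detection calls. The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set. The deposited intensities of each array, with the lowest and highest 2% of probe sets left out, had a mean of 99.95 to 99.96, the mark of an array scaled as a whole to a common target. Such scaling sets this trimmed mean equal but not the shape of the distributions, so bright transcripts can still differ between arrays for technical reasons.

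The table held 45101 probe sets, of which 64 were controls. Names came from the platform annotation: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Probe sets with no or several symbols and the controls were left out of the gene fit. Of the named probe sets, 34741 had a gene identifier found in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols needed an update. Together they named 18193 genes. No coordinates were used.

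Signals were log2-transformed after adding a pseudocount of 3.51, the 25th percentile of all values, so fold changes are on the log2(signal + pseudocount) scale and understate the change of dim genes. No further normalization between arrays was applied. Each gene was represented by its probe set with the highest mean signal, and genes were kept when that mean was at least 11.6, the median over all probe sets. This left 11942 genes. Differences, given as OGFRL1 minus EGFP, were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and 4.48 prior degrees of freedom. Levels are means ± SD of the deposited signals, and fold changes carry the standard error (SE) of the fit.

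Shifts of gene groups were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists with 3 or more tested members. The 43 lists were fixed before the data were examined, and 42 had enough members; 706 of their 794 entries were matched to the array. Camera was repeated with the correlation estimated from the data, a test that rests on only 2 residual degrees of freedom. A call lost there may be lost for want of degrees of freedom rather than through correlation between genes. The lists were also tested with fry, which asks whether the genes of a list moved, on balance in 1 direction or in either direction. Members were also counted after adjustment over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

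Genes are named by a rule that was fixed with the lists. It takes Ogfrl1, Ogfr, Alb, Acta2, Col1a1 and Mki67 always. In each direction it takes 12 genes past the threshold in order of absolute log2 fold change, with predicted genes skipped. Of each list described it takes up to 4 members, first those past the threshold over all genes and then those with the largest absolute moderated t. A gene named outside this rule is said to be chosen after its values were seen.

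The pipeline was tested on 5 simulated data sets of 11942 genes for the OGFRL1 against EGFP comparison, each with 200 changed genes. It called 19.6% of genes given a log2 change of 1 and 76% of those given a log2 change of 2, and 0 with the wrong sign. Over all data sets 478 changed and 31 unchanged genes were called. All 10 lists given a log2 shift of 0.5 were called, and 0 of 190 unshifted lists. The simulated genes varied independently of each other, which genes in tissue do not.

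Alternatives were quantile normalization, scaling to equal medians, a floor in place of the pseudocount, 4 times the pseudocount, no filter, a stricter filter, the mean over a gene's probe sets, no intensity trend, the replicate number as a block, each array left out in turn, and a fit of all probe sets. The labels give both groups replicates 1 and 2 but do not say that a number marks a shared animal, day or batch. They also do not say whether the arrays of a group came from separate mice, so the p-values measure only the spread between these arrays, part of which may be technical. With 2 arrays per group, the number of arrays limits the precision of every value.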

Results

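Regenerating livers of nude mice (BALB/c nu/nu, which lack mature T cells) were compared after transplantation of human bone marrow mesenchymal stem cells carrying either OGFRL1 or the control protein EGFP. Per the labels, the mice had received carbon tetrachloride, a hepatotoxin that causes fibrosis on repeated dosing, 23 times at 0.25 ml/kg, and 1000000 cells were placed in the spleen. Partial hepatectomy followed on day 21, and liver was taken on day 8 after it. The design asks how the transcriptome of the regenerating liver differs between the OGFRL1 group (n = 2 arrays) and the EGFP group (n = 2 arrays). Median signals were 12.5 and 12.2 on EGFP arrays 1 and 2, and 12.3 and 11.6 on OGFRL1 arrays 1 and 2. Across the 11942 genes tested, the Pearson correlation was 0.984 between the OGFRL1 arrays and 0.972 between the EGFP arrays. Pairs from different groups gave 0.965 to 0.973, and EGFP 2 with OGFRL1 1 was as close as the EGFP pair. These correlations are across genes, which are not independent replicates.

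The endogenous mouse gene Ogfrl1 had a signal of 128 ± 12.1 (SD) in EGFP livers and 123 ± 1.4 in OGFRL1 livers, a log2 fold change of -0.05 ± 0.16 (SE) with a limma adjusted p of 0.92. Ogfr, which encodes the opioid growth factor receptor, was at 256 ± 29.6 and 213.6 ± 3.0, a log2 fold change of -0.25 ± 0.15 (adjusted p = 0.493). Ogfrl1 was at -0.32 as the mean over its probe sets, -0.13 after quantile normalization, -0.16 with median scaling, 0.04 without EGFP 1 and -0.145 without EGFP 2, and Ogfr was at -0.14 without EGFP 1. The array carries mouse probe sets and the transplanted cells were human, so neither value checks the transgene.

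Differential expression was found for 61 genes between OGFRL1 and EGFP livers, of which 43 were higher and 18 lower in the OGFRL1 group. The largest increase was in Sult1e1, the oestrogen sulfotransferase, from 73.0 ± 43.6 (SD, n = 2) to 1089.5 ± 303 (log2 fold change 3.94 ± 0.40 SE, limma adjusted p = 0.0405). Psat1, an enzyme of serine synthesis, rose by 2.49 ± 0.30 on the log2 scale. Afp, the alpha-fetoprotein of fetal liver, rose from 71.5 ± 19.8 to 303 ± 15.5 (2.06 ± 0.21). Rgs2, a regulator of G protein signalling, rose by 1.87 ± 0.22, and Trim59 by 1.95 ± 0.21. The 7 others of the 12 largest increases were genes known from the cell cycle or from proliferation: Birc5 (2.36), Ect2 (2.23), Nuf2 (1.94), Rrm2 (1.87), Cip2a (1.83), Mad2l1 (1.83) and Mybl1 (1.81). The largest decrease was in Cyp4a12a, a fatty acid hydroxylase of male liver, from 1298.9 ± 498 to 81.2 ± 33.3 (-3.95 ± 0.35, adjusted p = 0.0364). Sult2a8, a hepatic sulfotransferase, went from 1628 ± 424 to 160.4 ± 29.9 (-3.30 ± 0.22, adjusted p = 0.0306). The log2 fold change was -2.89 ± 0.34 for Mup3, a major urinary protein, -2.38 ± 0.33 for Ugt3a1 and -2.10 ± 0.29 for Keg1. It was -2.04 ± 0.16 for Dct, known from melanin synthesis, and -1.99 ± 0.18 for the organic anion transporter Slc22a7. The chaperone Hspb1, Nat8, the serum amyloid Saa4, Cyp2c38 and the sterol desaturase Sc5d followed, with log2 fold changes from -1.48 to -1.10. Cyp4a12a, Mup3 and Saa4 have close paralogs whose transcripts may bind the same probes, so their gene assignment is uncertain.

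All 61 genes had both OGFRL1 arrays on the same side of both EGFP arrays, and their adjusted p lay between 0.0306 and 0.0498. At an unadjusted p under 0.05 the count was 1826, of which 1076 were higher. Over all genes tested 47.5% showed no overlap between the groups, where chance gives 33.3%. The number of calls changed with the normalization, the pseudocount, the filter, the variance model and the array left out. Quantile normalization called 4 genes (Rrm2, Cyp4a12a, Sult2a8 and Dct), 4 times the pseudocount 94, a stricter filter 2, and limma without a filter or without an intensity trend 0, with 2179 and 1654 genes at an unadjusted p under 0.05. Each of the 61 genes kept its direction in every setting that tested it. As the groups do not overlap in these genes, leaving out an array could not reverse them, so this adds no support.

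**Figure D1:**
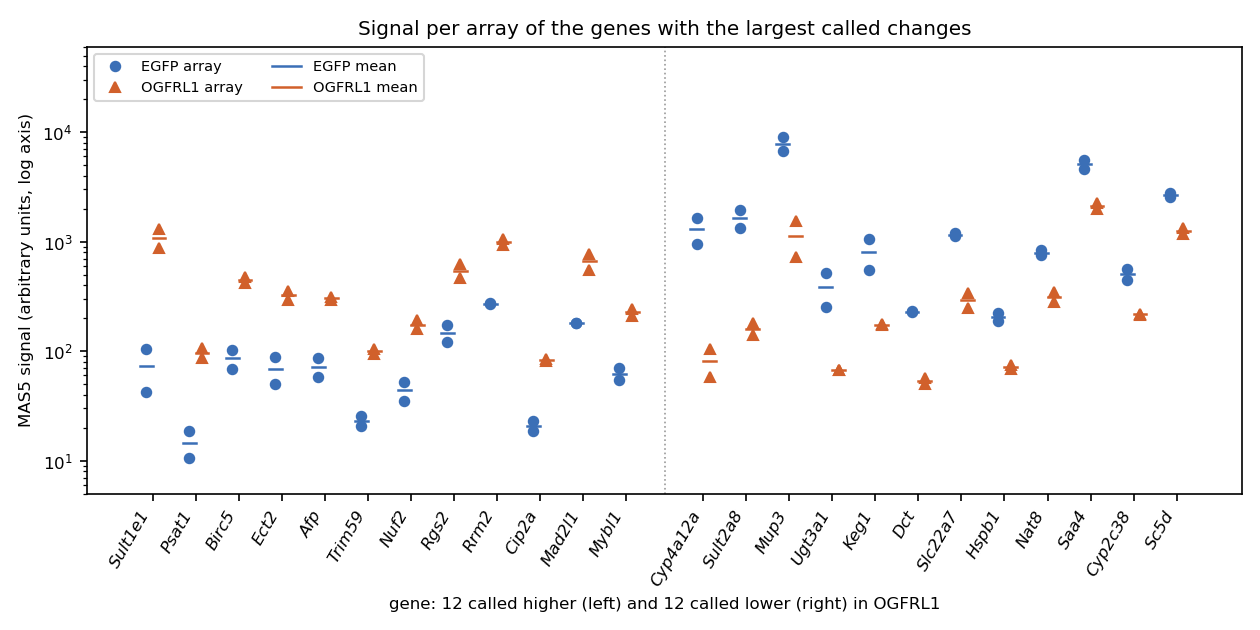
Signal (vertical, log axis, arbitrary MAS5 units) of the 12 genes with the largest called increases and the 12 with the largest called decreases (horizontal). Circles are the 2 EGFP arrays, triangles the 2 OGFRL1 arrays and short lines the group means. For each of these genes the arrays of the groups do not overlap, as for Sult1e1 with means of 73.0 and 1089.5.

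Genes of DNA replication were higher in OGFRL1 livers, with all 24 tested members above the EGFP group and a median log2 fold change of 1.10. Over all genes tested 7 passed the threshold, and 21 did when adjusted over the list alone. Rrm2, the small subunit of ribonucleotide reductase, rose from 270 ± 4.4 (SD) to 998 ± 88.0, or by 1.87 ± 0.14 (SE) on the log2 scale. Mcm6 and Mcm5, subunits of the replicative helicase, rose by 1.70 ± 0.18 and 1.25 ± 0.17, and the primase Prim1 by 1.29 ± 0.14. Genes of mitosis had a median of 1.59, with 20 of 21 members higher, 1 past the threshold over all genes and 20 adjusted over the list alone. That gene was Birc5, a subunit of the chromosomal passenger complex, which went from 85.6 ± 23.5 to 446.1 ± 35.0. Tpx2 (1.64 ± 0.24, adjusted p = 0.0523), Kif11 (1.49 ± 0.24) and Cdk1 (1.44 ± 0.23) did not pass over all genes. Mki67, a marker of cycling cells, had signals of 117 ± 58.1 and 400.8 ± 65.3 (1.83 ± 0.33, adjusted p = 0.0728). Camera gave an adjusted p of 7.88e-21 for replication and 9.14e-17 for mitosis. Neither call held with an estimated correlation (adjusted p = 0.361 and adjusted p = 0.498).

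Markers of cholangiocytes and liver progenitors were higher as a group (median 0.39, 10 of 12 members higher, camera adjusted p = 0.00751). Afp passed over all genes, and 3 members did adjusted over the list alone. Cd24a, a surface marker of progenitors, had a log2 fold change of 1.10 ± 0.16 (adjusted p = 0.0503), Prom1 of 1.94 ± 0.34 (adjusted p = 0.0692) and Krt18 of 0.46 ± 0.19. Other members, chosen after their values were seen, changed by about their standard errors or less. These were Epcam (-0.21 ± 0.22), Sox9 (-0.15 ± 0.345), Krt19 (0.30 ± 0.32), Krt7 (0.56 ± 0.54) and Krt8 (0.07 ± 0.23), so the rise was not shared by all markers of the list. YAP targets had a median of 0.25, with 11 of 14 higher (camera adjusted p = 0.00266), Afp, which is also a progenitor marker, past the threshold over all genes and 3 adjusted over the list alone. Ccn2, a matricellular growth factor, had a log2 fold change of 1.05 ± 0.16 (adjusted p = 0.0554), Ajuba of 0.98 ± 0.19 and Lats2 of 0.52 ± 0.16, which was -0.12 as the mean over its probe sets. Targets of p53 had a median of 0.31 with 11 of 13 higher (camera adjusted p = 0.0314), 0 past the threshold over all genes and 2 adjusted over the list alone. Among them Phlda3 had 1.04 ± 0.20, Plk2 0.81 ± 0.21, Ccng1 0.64 ± 0.19 and the pro-apoptotic Bbc3 -0.61 ± 0.19. All 3 calls were lost with an estimated correlation (adjusted p = 0.424 for progenitor markers, adjusted p = 0.504 for YAP targets and adjusted p = 0.584 for p53 targets). The YAP call was also lost without EGFP 2 (median 0.07), while the median was 0.42 without EGFP 1, 0.41 without OGFRL1 1 and 0.15 with median scaling. The p53 call was lost without EGFP 2 (0.10), without OGFRL1 1 (0.32) and with the mean over probe sets (0.26), while its median was 0.55 without OGFRL1 2 and 0.21 with median scaling, and the progenitor median was 1.10 under the stricter filter. Krt18 had 0.71 after quantile normalization and 0.24 without EGFP 2, and Ccng1 had 0.39 without EGFP 1 and 0.42 as the mean over its probe sets.

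Genes of fibrillar collagen and matrix were higher in OGFRL1 livers (median 0.62, 23 of 25 members higher, camera adjusted p = 8.32e-08). None passed the threshold over all genes, and 8 did adjusted over the list alone. Col1a1, a chain of type I collagen, had signals of 34.5 ± 10.8 (SD) and 148.2 ± 40.5, a log2 fold change of 2.002 ± 0.285 (SE) that missed the threshold (limma adjusted p = 0.0503). Col6a3 had 1.15 ± 0.26, Fstl1 0.94 ± 0.16 and Col5a1 0.85 ± 0.18. Brighter members, chosen after their values were seen, changed less than Col1a1. Col1a2, the other chain of type I collagen, was at 741 ± 115 and 1400 ± 568.5 (0.86 ± 0.28, adjusted p = 0.222). Col3a1 was at 1041 ± 140 and 1746 ± 364 (0.735 ± 0.188), while Fn1 (-0.03 ± 0.15) and Dcn (-0.004 ± 0.229) did not change. Markers of stellate cells and myofibroblasts, the collagen-producing cells of liver, had a median of 0.38 with 14 of 17 higher (camera adjusted p = 0.00365), 0 past the threshold and 6 adjusted over the list alone. Acta2, the smooth muscle actin of myofibroblasts, was at 92.0 ± 21.5 and 205.8 ± 10.3 (1.15 ± 0.20, adjusted p = 0.0684), Tagln had 1.37 ± 0.28, Pdgfrb 0.99 ± 0.20 and Vim 0.90 ± 0.16. Other members, chosen after their values were seen, did not rise beyond their standard errors. These were Lrat (-0.08 ± 0.17), Ecm1 (0.07 ± 0.25), Colec11 (0.025 ± 0.139), Rgs5 (-0.405 ± 0.170) and Angptl6 (-0.57 ± 0.23), so the rise was not shared by all markers of the list. Genes of the TGF-beta response had a median of 0.64 with 12 of 13 higher (camera adjusted p = 4.9e-05), 0 past the threshold and 7 adjusted over the list alone, among them Ltbp1 (1.35 ± 0.32), Ccn2, Id1 (0.96 ± 0.20) and Ltbp2 (0.92 ± 0.27). Matrix-degrading proteases had a median of 0.41 with 12 of 14 higher (camera adjusted p = 0.0393) and 0 members past either adjustment. Plat, the tissue plasminogen activator, had 1.15 ± 0.26, Mmp12 0.74 ± 0.24, Mmp2 0.40 ± 0.20 and the cathepsin Ctsl -0.35 ± 0.16. The 4 calls were lost with an estimated correlation, where the adjusted p was 0.504 for matrix, 0.401 for stellate cells, 0.541 for TGF-beta and 0.738 for proteases. Without OGFRL1 2 the medians were 0.40 for matrix, 0.22 for stellate cells and 0.12 for proteases, the last no longer called, nor was it without EGFP 2 (0.30) or under the stricter filter (0.33). The protease median was 0.72 without OGFRL1 1, and that of the TGF-beta response 0.39 without EGFP 2 and 0.41 under the stricter filter and 4 times the pseudocount. Among the genes, Col6a3 had 0.765, Mmp12 0.45 and Mmp2 0.21 without OGFRL1 2, Col5a1 0.52 as the mean over its probe sets, and Ctsl -0.02 after quantile normalization and -0.19 without EGFP 1.

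Cholesterol synthesis was lower in OGFRL1 livers, with 17 of 18 members of the list below the EGFP group and a median log2 fold change of -0.91 (camera adjusted p = 4.26e-16). Sc5d and Fdps, the farnesyl diphosphate synthase, passed the threshold over all genes, and 17 members did adjusted over the list alone. Sc5d went from 2676 ± 157 (SD) to 1248 ± 109.5 and Fdps from 2513 ± 302 to 1176 ± 8.9, log2 fold changes of -1.10 ± 0.14 (SE) and -1.09 ± 0.14, but as the mean over its probe sets Sc5d was at -0.66 and not called (adjusted p = 0.106). Fdft1, the squalene synthase, had -0.95 ± 0.15 (adjusted p = 0.0554) and Hmgcs1 -0.95 ± 0.16. Fatty acid synthesis had a median of -0.53 with 16 of 19 members lower (camera adjusted p = 8.32e-08), 0 past the threshold over all genes, and 10 lower and 1 higher adjusted over the list alone. The elongase Elovl3 had -2.07 ± 0.30 (adjusted p = 0.0512), Acacb -1.16 ± 0.18, the lipogenic factor Thrsp -0.85 ± 0.13 and Elovl5 -0.68 ± 0.14. Bile acid synthesis and transport had a median of -0.36 with 13 of 17 lower (camera adjusted p = 0.000387), 0 past the threshold over all genes, and 5 lower and 1 higher adjusted over the list alone. Cyp7b1, an oxysterol hydroxylase, had -1.74 ± 0.35, Slc27a5 -0.88 ± 0.13, Cyp27a1 -0.73 ± 0.19 and the bile acid carrier Slco1b2 -0.68 ± 0.15. The bile acid median lay between the means of the spike-in controls described below, -0.43 for Cre and -0.32 for BioB, BioC and BioD. Set against the spike-ins that list thus showed no fall of its own, while the median over all tested genes was 0.04. A shift common to all genes would not make the call, as camera compares a list with the other genes. None of these calls held with an estimated correlation (adjusted p = 0.361 for cholesterol, adjusted p = 0.361 for fatty acids and adjusted p = 0.395 for bile acids).

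Abundant hepatocyte transcripts were lower in OGFRL1 livers. All 19 secreted hepatocyte proteins were below the EGFP group (median -0.53, camera adjusted p = 3.49e-11), with 0 past the threshold over all genes and 15 adjusted over the list alone. Alb, serum albumin, was at 12710 ± 4804 (SD) and 7486 ± 629 (-0.71 ± 0.26 SE, limma adjusted p = 0.271), C8a had -0.69 ± 0.18, Plg -0.55 ± 0.16, F2, prothrombin, -0.50 ± 0.15 and Itih1 -0.46 ± 0.13. The bright Cre spike-in controls, which standard protocols add in equal amounts, were also lower, with a mean log2 fold change of -0.43 over 4 probe sets, and the 14 dimmer BioB, BioC and BioD probe sets had a mean of -0.32. Among 134 genes with a mean signal over 5000, 128 were below 0, with a median of -0.43. Oxidative phosphorylation had a median of -0.30 with 19 of 19 lower (camera adjusted p = 1.54e-07) and 0 members past either adjustment, with Uqcrc1 at -0.53 ± 0.15, Atp5a1 at -0.52 ± 0.14, Sdhb at -0.43 ± 0.14 and Sdha at -0.38 ± 0.14. Hepatocyte transcription factors had a median of -0.16 with 11 of 15 lower (camera adjusted p = 0.019) and 0 past either adjustment, with Cebpa at -0.70 ± 0.22, Hnf4a at -0.55 ± 0.15, Nr1h4 at -0.36 ± 0.20 and Foxa3 at -0.26 ± 0.13. The medians of oxidative phosphorylation and of transcription factors fell by less than the means of the bright and the dimmer spike-ins. When the correlation was estimated from the data these calls were lost, with adjusted p = 0.471 for secreted proteins, 0.361 for oxidative phosphorylation and 0.522 for transcription factors. Quantile normalization brought the medians of secreted proteins and oxidative phosphorylation to -0.12 and -0.14, and without EGFP 1 the first was -0.32. The transcription factor call was lost without EGFP 2 (median -0.09) and without OGFRL1 2 (-0.11), and its median was -0.26 with median scaling. Alb had -0.32 without EGFP 1 and -1.11 without EGFP 2, and quantile normalization left it at -0.16, Plg at -0.12, F2 at -0.20 and Sdhb at -0.28. Cebpa had -0.38 without EGFP 2, Nr1h4 -0.61 without OGFRL1 1 and -0.12 without OGFRL1 2, and Hnf4a -0.20 as the mean over its probe sets.

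Zonated and drug-metabolising genes were lower in the same arrays as the spike-in controls. Pericentral genes had a median of -0.24 with 13 of 17 lower (camera adjusted p = 0.000246), 0 past the threshold over all genes and 7 adjusted over the list alone. Cyp2e1 had a log2 fold change of -0.79 ± 0.15, Cyp27a1 of -0.73 ± 0.19, Slco1b2 of -0.68 ± 0.15 and Gulo of -0.59 ± 0.15. Periportal genes had a median of -0.27 with 13 of 15 lower (camera adjusted p = 0.000109), 0 past the threshold and 3 adjusted over the list alone. Cyp2f2 had -0.85 ± 0.17, Pigr and the urea cycle enzyme Otc both -0.66, and Hal -0.44 ± 0.15. P450 and conjugation genes had a median of -0.29 with 14 of 17 lower (camera adjusted p = 0.00115), Cyp2c38 past the threshold over all genes, and 2 lower and 1 higher adjusted over the list alone. Cyp2c38 fell by 1.21 ± 0.16, Ugt2b1 had -0.81 ± 0.17 and Cyp2c29 -0.71 ± 0.23, while Cyp1a1, a target of the aryl hydrocarbon receptor, had 1.65 ± 0.25 (adjusted p = 0.0552). Acute phase genes had a median of -0.40 with 19 of 23 lower (camera adjusted p = 2.44e-06), 0 past the threshold and 2 adjusted over the list alone. Saa2 had -1.89 ± 0.44, Saa1 -1.04 ± 0.20, Itih4 -0.50 ± 0.15 and Crp -0.43 ± 0.13. The acute phase median lay between the means of the spike-in controls (-0.43 for Cre and -0.32 for BioB, BioC and BioD). The pericentral, periportal and P450 medians fell by less than both. The calls did not hold with an estimated correlation, where the adjusted p was 0.498 for pericentral, 0.361 for periportal, 0.584 for P450 and 0.6 for acute phase genes. Quantile normalization ended the periportal, P450 and acute phase calls, with medians of -0.06, -0.08 and -0.01, and gave -0.38 for Cyp2e1, -0.50 for Cyp2f2, -0.21 for Cyp2c29, -0.28 for Crp and -0.125 for Itih4. Cyp2c29 had -0.38 without EGFP 1 and Saa2 -1.135 without OGFRL1 1. The P450 call was also lost without EGFP 1 (-0.11) and without OGFRL1 2 (-0.15), and its median was -0.50 without OGFRL1 1, while the acute phase median was -0.17 without EGFP 1 and -0.64 without EGFP 2. The pericentral median was -0.06 without EGFP 1, -0.51 without EGFP 2, -0.44 without OGFRL1 1 and -0.11 without OGFRL1 2, and -0.44 under the stricter filter.

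Male-biased liver genes were lower in OGFRL1 livers (median -0.81, 9 of 12 members lower, camera adjusted p = 3.76e-06). Cyp4a12a and Mup3 passed the threshold over all genes, and 8 lower and 1 higher member did adjusted over the list alone. Mup3 went from 7866 ± 1527 (SD) to 1126 ± 570, and Elovl3 and Cyp7b1 had the values given above. The 3 members that were higher were the Y-linked genes Eif2s3y (1.04), Uty (0.33) and Kdm5d (0.11), chosen here after their values were seen. Heat shock genes were lower in 12 of 12 members (median -0.40, camera adjusted p = 4.93e-06), with Hspb1 past the threshold over all genes and 4 adjusted over the list alone. Hspb1 went from 205.2 ± 24.7 to 71.3 ± 4.5, Hspa1a had -2.14 ± 0.53, Hspa1b -1.90 ± 0.44 and Bag3 -0.57 ± 0.18. Hspa1a and Hspa1b are near-identical copies, so their signals cannot be assigned to either with certainty. Interferon response genes had a median of -0.41 with 16 of 20 lower (camera adjusted p = 0.00365) and 0 members past either adjustment. Igtp, an interferon-induced GTPase, had signals of 6232 and 1508 in EGFP 1 and 2, and 1122 and 1089 in OGFRL1 1 and 2. Iigp1 had -1.19 ± 0.37, Irgm1 -0.95 ± 0.40 and Ifit1 -0.77 ± 0.24. The 3 calls were lost with an estimated correlation (adjusted p = 0.361 for male-biased genes, adjusted p = 0.541 for heat shock and adjusted p = 0.738 for interferon). The heat shock and interferon medians also lay between the means of the spike-in controls (-0.43 for Cre and -0.32 for BioB, BioC and BioD). The heat shock median was -0.24 without OGFRL1 1, where Hspa1a had -1.29, Hspa1b -1.21 and Bag3 -0.36, and -0.65 without OGFRL1 2. Without EGFP 1 the interferon list was not called (median 0.05, adjusted p = 0.632), and its median was -0.98 without EGFP 2, -0.22 without OGFRL1 1, -0.79 without OGFRL1 2 and -0.77 under the stricter filter. Without EGFP 1, Iigp1 had -0.56, Irgm1 -0.28 and Ifit1 -0.45, and without EGFP 2 the first and second had -1.82 and -1.61.

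**Figure D2:**
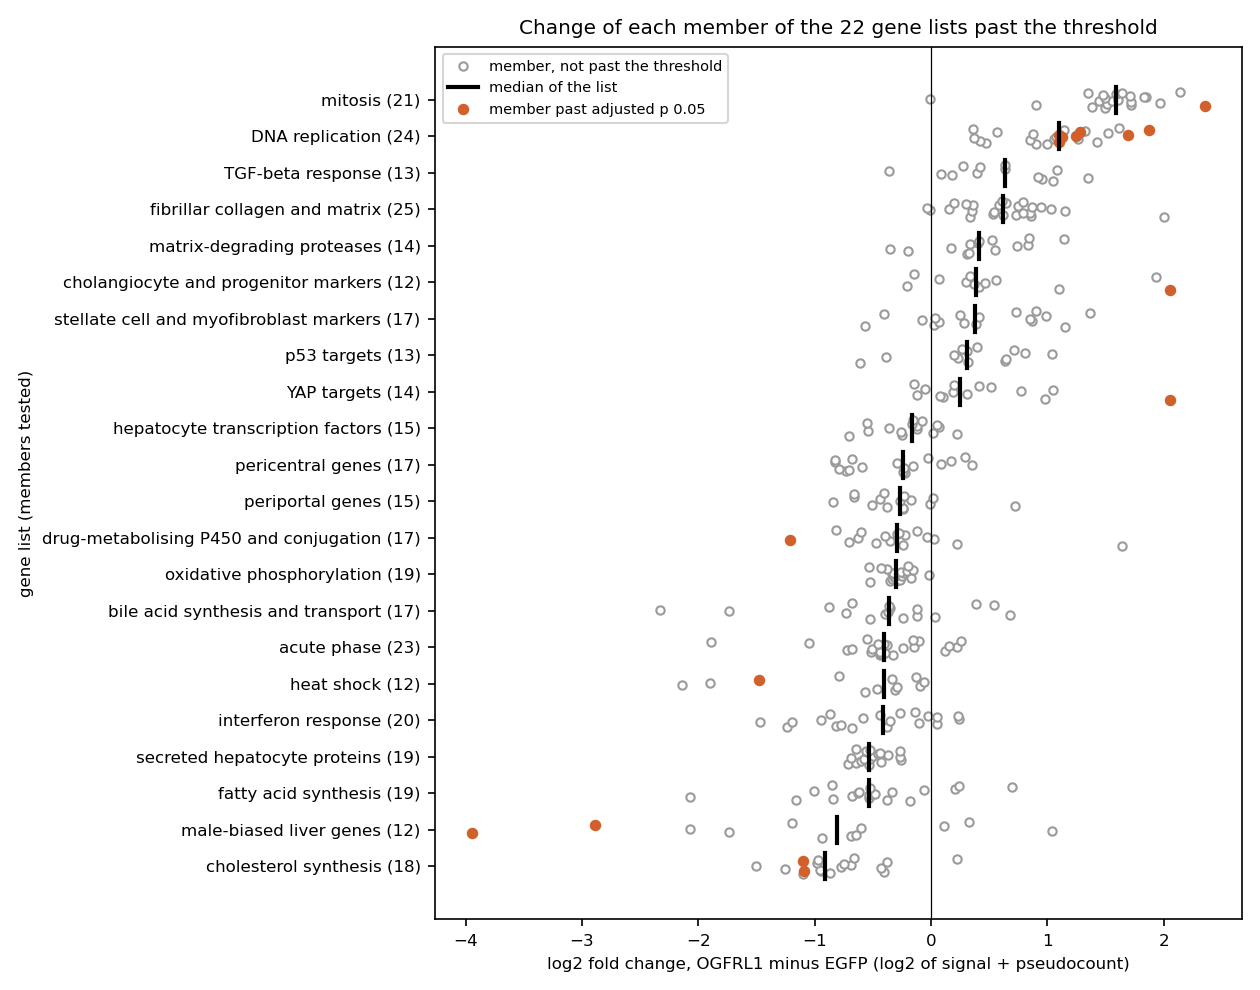
Log2 fold change (horizontal, OGFRL1 minus EGFP) of every tested member of the 22 gene lists past the threshold (vertical, number of members in brackets), with 1 point per gene. Filled points passed adjusted p 0.05 over all genes, and black lines are list medians, which run from -0.91 for cholesterol synthesis to 1.59 for mitosis.

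Of the 42 lists tested, 22 passed with the preset correlation, 9 higher and 13 lower in OGFRL1 livers. With an estimated correlation 0 passed, at a lowest adjusted p of 0.361. That test had 2 residual degrees of freedom and so little power. Lists with an estimated correlation below the preset 0.01 were lost too, such as male-biased genes (-0.03) and periportal genes (-0.05). The losses thus do not show that correlation between genes made the calls. By fry 0 passed for a balance of change in 1 direction, at a lowest adjusted p of 0.0525, and 14 for change in either direction, 10 of them among the 22 and 4 not: fatty acid oxidation, erythroid markers, regeneration ligands and receptors, and lipid storage. The 20 lists that did not pass with the preset correlation covered other cell types and pathways. Female-biased liver genes had a median of 0.42 (adjusted p = 0.0843), mesothelial and adipose markers 0.30, skeletal and smooth muscle markers 0.29, immediate early genes 0.24, apoptosis and senescence 0.18, lipid storage 0.18 and macrophage and Kupffer cell markers 0.16. Ribosomal proteins had a median of 0.11, regeneration ligands and receptors 0.10, gluconeogenesis and glycolysis 0.10, endothelial markers 0.06 and pancreas and gut markers 0.01. Medians below 0 were found for erythroid markers (-0.04), circadian clock genes (-0.05), the unfolded protein response (-0.09), neutrophil markers (-0.09), fatty acid oxidation (-0.11), NRF2 targets (-0.15), T and NK cell markers (-0.27) and B and plasma cell markers (-0.43). With 1 array left out, 8 of these lists passed: macrophage markers (median 0.72) and immediate early genes (0.35) without EGFP 1; female-biased genes (0.59), B and plasma cell markers (-0.80), the unfolded protein response (-0.24), NRF2 targets (-0.28) and neutrophil markers (-0.52) without EGFP 2; macrophage markers (0.51), immediate early genes (0.43) and erythroid markers (-0.66) without OGFRL1 1; and female-biased genes (0.36) and B and plasma cell markers (-0.36) without OGFRL1 2. For 3 of the lists that did not pass, the regeneration ligands and receptors, endothelial markers and pancreas and gut markers, camera gave the direction opposite to the median. The opioid growth factor axis, with fewer than 3 tested members, was not tested as a list.

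The 3 prime over 5 prime signal ratio, a measure of RNA integrity, lay on both OGFRL1 arrays within the range of the EGFP arrays. For Gapdh it was 0.760 ± 0.0374 (SD, n = 2) in EGFP and 0.753 ± 0.0211 in OGFRL1 livers, and for Actb it was 1.76 ± 0.260 and 1.69 ± 0.00520. The 3 prime Cre spike-in probe set gave 7803 ± 566 and 5832 ± 524, with both OGFRL1 arrays below both EGFP arrays.

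**Figure D3:**
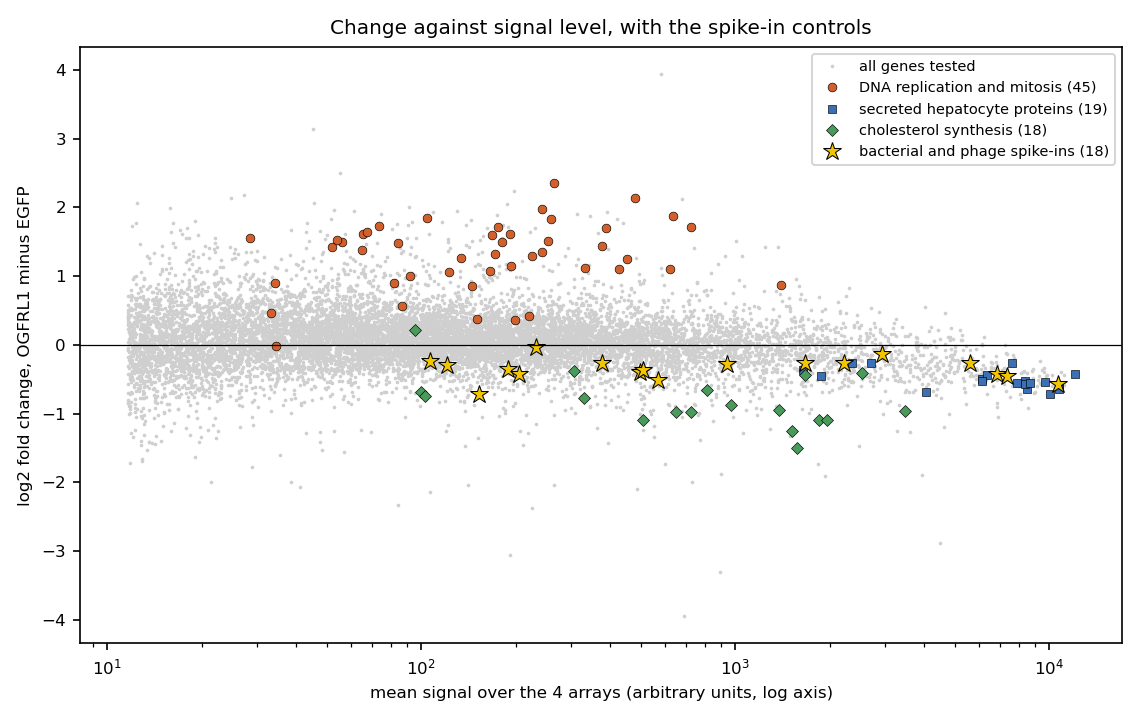
Log2 fold change (vertical, OGFRL1 minus EGFP) against mean signal over the 4 arrays (horizontal, log axis, arbitrary units), with 1 point per gene or spike-in probe set. Genes of DNA replication and mitosis (circles) lie mostly above 0, secreted hepatocyte proteins (squares) lie below 0 beside the 4 bright Cre spike-ins (stars, mean -0.43), and most genes of cholesterol synthesis (diamonds) lie lower still.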

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

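The tests of explanations and the other splits of the arrays in this part were chosen after the results were seen.

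The fit over all 22516 probe sets called 1 probe set that the gene fit left out because the platform annotation gives it no gene symbol or several. It had signals of 134.9 and 131.3 on the EGFP arrays and 363.9 and 330.8 on the OGFRL1 arrays (log2 fold change 1.36 ± 0.15 SE, limma adjusted p = 0.0474). It stood out as a signal above the control group in data that the comparisons by gene do not use.

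The 45 cell cycle genes of the replication and mitosis lists were higher in OGFRL1 livers, with a median log2 fold change of 1.39. The scaling of the arrays is argued against, because the lowest median over the 3 scalings was 1.28. Dividing erythroid precursors, which regenerating liver could hold, would bring their own transcripts, and the largest increase among the 6 tested erythroid markers was 0.46. What stays open is whether the livers were at different stages of regeneration regardless of the cells given: the EGFP arrays differed by a median of 0.35 in these genes, which joins 0.95 in mitosis genes and 0.03 in replication genes, against 1.59 and 1.10 between the groups, and with 2 arrays per group the stage of an animal and its treatment cannot be told apart. Of the 3 splits of the 4 arrays into pairs, 1 gave as many as 61 genes, the real one, and the highest of the others gave 0 by limma (88 and 553 genes at an unadjusted p under 0.05), but 3 splits are too few for a share under 0.05.

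Abundant hepatocyte transcripts were lower in OGFRL1 livers, and the spike-in controls were lower too. The brightness or scaling of the arrays may account for much of this, because the 4 Cre spike-ins, as bright as these transcripts, had a mean log2 fold change of -0.43. Quantile normalization moved the median of secreted proteins from -0.53 to -0.12. It makes the bright ends of the arrays equal, where these transcripts lie, so it would shrink a real fall too and cannot tell the causes apart. The 14 dimmer spike-ins were lower too, with a mean of -0.32 and a range from -0.72 to -0.03, while the median over all tested genes was 0.04. As every array was scaled to about the same trimmed mean, whether the spike-ins fell or the genes as a whole rose cannot be told. Fewer hepatocytes with no other change would raise the markers of other cell types alike, and this was not seen. Stellate cell markers had a mean of 0.43 and endothelial markers of 0.06 (2-sided permutation test with 100000 resamples, p = 0.0157, genes not being independent replicates). The test cannot exclude fewer hepatocytes together with a change in stellate cells. That, an increase of stellate cells alone, or lower expression in hepatocytes stays open. Of the stellate markers 14 of 17 were higher, but Lrat (-0.08 ± 0.17) and Rgs5 (-0.405 ± 0.170) were not.

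Male-biased liver genes were lower in OGFRL1 livers, with a median of -1.47 over the 8 that are neither Y-linked nor in the list of secreted hepatocyte proteins. A difference in sex between the animals is argued against, because the highest Xist signal was 11.2, below the lowest mean signal kept, while the 3 tested Y-linked genes lay between 65.4 and 465.4 on every array. Brightness or a lower hepatocyte share alone is also argued against, because these genes fell further than the 19 genes of that list. Secreted proteins lie near the top of the signal range, where changes can be understated, but the dimmer hepatocyte transcription factors had a median of -0.16. The means of the male-biased and the secreted genes were -1.75 and -0.50 (2-sided exact permutation p = 1.17e-05 across genes, which are not independent replicates). The 8 genes include Cyp4a12a and Mup3, whose large falls were seen before this test was chosen, so its p-value is not independent support. The median of the male-biased genes was -1.46 after quantile normalization. An effect of the cells given and a difference between individual mice unrelated to the cells both stay open, as untested explanations, with 2 arrays per group.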

How the results depend on the processing

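The crossed pairing and the tests by other splits were chosen after the data were seen, and the other alternatives before. The count of called genes ran from 0 to 934 over 14 alternatives, against 61. The 934 came from the crossed pairs (EGFP 1 with OGFRL1 2, and EGFP 2 with OGFRL1 1). The count was 4 with quantile normalization, 47 with median scaling, 47 with a floor in place of the pseudocount and 94 with 4 times the pseudocount. It was 0 without a filter (2179 genes at an unadjusted p under 0.05), 2 with the stricter filter, 52 with the mean over probe sets and 0 without the intensity trend (1654). The fit over all probe sets called 44. Leaving out 1 array gave 0 to 856 genes: 619 without EGFP 1, 856 without EGFP 2, 0 without OGFRL1 1 (922 at an unadjusted p under 0.05) and 2 without OGFRL1 2, where the lone array of a group is assumed to vary like the other group. All 61 genes kept their direction in every alternative that tested them, 56 of them under the stricter filter. With 1 array left out this follows from the lack of overlap between the groups. In the alternatives with all arrays they also kept an unadjusted p under 0.05. Median scaling moved the median of all genes from 0.04 to -0.07 and the share of called genes that were higher from 70.5% to 57.4%, while quantile normalization left 1 gene higher and 3 lower.

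Of the genes named, 28 were called, against 4 with quantile normalization, 0 without a filter, 2 with the stricter filter, 0 without the trend and 0 to 77 with 1 array left out. The direction of Lats2 was reversed by the mean over probe sets (-0.12), and mouse Ogfrl1 ran from -0.145 to 0.044 with 1 array left out and was -0.321 as the mean over probe sets. Of the 102 genes named, 31 moved by over 1.5 times in some alternative, 20 of them with 1 array left out. Among the 28 called, Sc5d did, at -0.661 as the mean over probe sets. The cause was not tested. Against 22 called lists, the alternatives of the gene fit called 20 to 24 with the preset correlation. All 22 kept the direction camera gave, although the interferon median was 0.045 without EGFP 1, and 14 of them stayed past the threshold throughout. Camera with an estimated correlation called 0, fry 0 for a balance in 1 direction and 14 for change in either direction, 10 of them among the 22. The other 2 splits of the arrays called 6 and 10 lists with the preset correlation, so it also calls lists between pairs that each hold 1 array of either treatment.

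The lists that reversed were not among the 22. Quantile normalization reversed NRF2 targets (-0.04) and median scaling neutrophil markers (-0.19). Without a filter, endothelial markers (0.062), pancreas and gut markers (0.052) and muscle markers (-0.093) reversed, as did erythroid markers with the stricter filter (0.22), pancreas and gut markers without the trend (0.011) and endothelial markers with crossed pairs (0.062), by camera's direction. With 1 array left out, medians ran from -0.28 to 0.10 for NRF2 targets, -0.24 to 0.05 for the unfolded protein response, -0.52 to 0.40 for neutrophils, -0.80 to 0.33 for B and plasma cells, -0.11 to 0.16 for pancreas and gut, -0.016 to 0.433 for immediate early genes, -0.41 to 0.72 for macrophages, -0.081 to 0.083 for endothelium, -0.057 to 0.080 for the circadian clock and 0.085 to 0.274 for lipid storage. The cause was not tested. Of the 20 other lists, 9 passed in at least 1 alternative: female-biased genes in 7, B and plasma cells in 3 (crossed pairs, without EGFP 2 and without OGFRL1 2), macrophages and immediate early genes in 2 each (without EGFP 1 and without OGFRL1 1), NRF2 targets, the unfolded protein response and neutrophils without EGFP 2, erythroid markers without OGFRL1 1 and ribosomal proteins with quantile normalization (0.27).

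With the replicate number as a block, 59 genes (38 of the 61) and 23 lists were called. Same-numbered arrays deviated from their group means with a correlation of -0.276 across genes, so the numbers do not pair the arrays. Crossed pairs called 934 genes, 85 named genes and 24 lists. The arrays of a crossed pair deviate together by that same correlation, so this block lowers the residual spread and its calls add no support. The mean correlation within groups exceeded that between groups by 0.0096, and by 0.0039 over all probe sets, which include signals near background.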

Other observations

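The genes and groups in this part were chosen after their values were seen, and Slc1a4, Psat1 and Bex1 are the ones among them past the threshold. Slc1a4, a carrier of serine and other neutral amino acids, rose in OGFRL1 livers (log2 fold change 1.54 ± 0.16 SE, limma adjusted p = 0.0405), as did Psat1. Other genes of serine synthesis had smaller values, with Phgdh at 0.91 ± 0.50, Psph at 0.57 ± 0.14 and Shmt2 at 0.02 ± 0.14. Bex1 rose from 62.0 ± 1.6 (SD) to 215.5 ± 14.2 (1.74 ± 0.16, adjusted p = 0.0364), and the imprinted gene Peg3 had 1.16 ± 0.18 (adjusted p = 0.0554). The intestinal cadherin Cdh17 had signals of 13.7 and 1.9 in EGFP livers and 70.8 and 95.0 in OGFRL1 livers (3.15 ± 0.54, adjusted p = 0.0684). Among receptors and carriers of growth factors, Egfr had -1.32 ± 0.26 (adjusted p = 0.0911) and Igfals -0.94 ± 0.15 (adjusted p = 0.0581). Ghr, the growth hormone receptor, had -0.85 ± 0.19 and Igf1 -0.36 ± 0.14, while Socs2, a target of growth hormone signalling, had 0.32 ± 0.35. Others went the other way, with Igfbp1 at 1.29 ± 0.41, Lepr at 0.755 ± 0.281 and Met at 0.11 ± 0.20. Of the 19 tested members of the list of regeneration ligands and receptors, 11 were higher and 8 lower. Of the erythroid and heme genes, Car1 had -2.001 ± 0.302 and Alas2 -1.45 ± 0.24, and Tfrc had 0.45 ± 0.14.

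Several macrophage genes differed more within the groups than between them. C1qa had signals of 1881 in EGFP 1 and 716.1 in EGFP 2, and of 845.7 in OGFRL1 1 and 1698 in OGFRL1 2. Lyz2 had 4533, 1400, 2108 and 3747 in the same order, and Cd5l 2005, 755.0, 952.5 and 1325. Between the groups the log2 fold change was 0.05 ± 0.49 for C1qa, 0.16 ± 0.54 for Lyz2 and -0.13 ± 0.43 for Cd5l. EGFP 1 and OGFRL1 2 were thus the arrays with the higher signals of these genes. Other macrophage markers were higher on both OGFRL1 arrays, such as Trem2 (1.04 ± 0.30), Gpnmb (0.59 ± 0.18) and Cx3cr1 (0.58 ± 0.195). Of the 23 markers tested, 15 were higher and 8 lower in the OGFRL1 group. Lgals3, also expressed by other cells, had 631.2, 449.9, 1086 and 1355.5 (1.18 ± 0.20, adjusted p = 0.0684). The interferon-induced Iigp1 had 9327, 3892.5, 2664.5 and 2605.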
